A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

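Two-colour tiling arrays were hybridised with material from 1 yeast strain, MDY510 with Myc-tagged H3, in 1 group of 2 arrays. Per the labels' protocols, chromatin of alpha factor-arrested cells was sheared by sonication, precipitated with a monoclonal anti-Myc antibody, amplified linearly from up to 75 ng and labelled from 3 µg of amplified RNA. The labels give Cy5 to the Myc-H3 IP and Cy3 to the sonicated input (WCE) on both arrays, with no dye swap, so a dye effect cannot be separated from the IP. Both arrays lay on 1 slide, so no batch could be tested. Linear amplification and labelling can each favour some sequences, and without a dye swap any such bias stays in the ratio.

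The spot intensity values were written by Agilent Feature Extraction 9.1.3.1 on array design 014810, per the file headers. The processed signals were background-subtracted, spatially and multiplicatively detrended and linearly dye-normalised within each array, per the file headers. The authors' deposited value table holds log2 ratios. These equal the log2 ratio of the processed Cy5 over Cy3 signals with a difference of at most 5.00e-06 at any probe, so its scale and direction are known and it is not centred (medians 0.03 and -0.00). The scanner files also hold 3444 control spots per array, which were left out of all tests.

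Log2 ratios of the processed signals were centred on each array's median, with no loess or quantile step, since most probes of such an array carry signal. Probes were left out where either channel was marked non-uniform or a population outlier on either array, or where Cy3 was not well above background on both arrays. This kept 40890 of 41775 probes: 29599 coding, 5746 in tandem promoters, 3328 in divergent promoters, 1862 downstream of genes, 125 without annotation and 230 of 295 mitochondrial ones. More than 99.7% of probes were well above background in each channel. Saturated spots, 6.14% and 8.49% in Cy5 and 6.11% and 4.74% in Cy3, were kept, and ratios of such spots are compressed. Of the mitochondrial probes kept, 87 were saturated in Cy5 on both arrays.

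Classes came from the array's own annotation of each probe. Of 1276 genes with downstream probes, 91.9% had their next gene on the opposite strand in the R64 gene table, against 7.13% of 2566 genes with tandem promoter probes, so the downstream class is called convergent here. The genome build of the probe coordinates is not given in the sources used here, so the R64 gene table served only for names and gene order. Of 5689 gene names on the array, 5663 matched it, 119 of them by a synonym. Intergenic regions with a tRNA gene were found by gene order, as the 273 gaps between neighbouring genes on the array with a tRNA gene between them. Centromeres and replication origins were not analysed here.

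Gene values were the mean of a gene's kept probes, from at least 2 coding probes or at least 1 promoter probe, and a divergent promoter counted for both genes. The genes of such a pair can thus hold the same promoter value, and promoter counts and list tests treat them as separate genes. Probes and genes were tested against 0 with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit drew every row's variance to a common value, with an SD of 0.05 for probes, 0.03 for coding regions and 0.05 for promoters. The test therefore asks whether a value exceeds the common spread between these 2 arrays, and small differences pass it. Class differences were tested by a two-sided exact sign-flip permutation test over the 16 nuclear chromosomes. It treats chromosomes as units and does not measure the spread between cultures. The test weighs each chromosome's difference equally, whereas the differences printed pool the probes of all chromosomes. The mitochondrial difference was a difference of medians with no test.

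Gene lists were fixed before the data were examined: ribosomal protein, mitochondrial ribosomal protein, glycolysis and fermentation, pheromone response, alpha-cell-specific, galactose, histone, G1/S, G2/M and M/G1, meiosis and sporulation, ribosome biogenesis, heat shock and stress, phosphate, hexose transporter, respiration, translation factor, proteasome and seripauperin genes. They were tested with camera at a preset correlation of 0.01 and compared with 10000 random lists matched on Cy3 signal. The random lists compare medians, whereas camera compares means. Cy3 is also the denominator of the ratio, so matching on it can take away part of a difference. The alpha-cell-specific and histone lists had too few coding regions measured for a test. The text names genes by a rule fixed at the same time: the 10 highest and 10 lowest coding regions and the 5 highest and 5 lowest promoters past the test, up to 2 highest and 2 lowest members of each list, GAL1, GAL10, GAL7, FUS1, PHO5, the H3 genes and strain marker loci. From these a part is printed.

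On data simulated for the 4996 coding regions, 100% of genes shifted by 0.1, 0.3, 0.6 or 1 (log2) were called, with 16 false calls. For the 5171 promoters, 62% were called at a shift of 0.1 and 100% at 0.3 and above, with 12 false calls. A shift of 0.5 in ribosomal protein genes was called by camera with 0 other lists, in coding regions and in promoters. The sign-flip test gave p under 0.05 in 119 of 2000 draws with no effect. All simulated values were independent and normal. Every gene had the same spread between arrays, and in the gene tests unshifted genes lay at 0. The simulations therefore check the calculation only. They do not show how the tests behave where genes are related or differ in spread, as they may in these data.

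Alternatives planned before the data were examined were normexp background correction of the mean signals (offset 50), which also leaves out the scanner software's detrending and dye normalisation, loess after it, the authors' value table, other filters on dim probes, each array alone, centring on the mode, an intensity trend in eBayes, other windows for chromosome ends, at least 1 coding probe per gene and other list tests. Alternatives chosen after seeing the data were leaving out saturated probes, 60-nt probes only, dimness in both channels and the turned sign, as were the tRNA classes by gene order and the profile by probe order. Probes shorter than 60 nt had higher ratios than 60-nt probes, by 0.16 ± 0.003 in coding regions and 0.24 ± 0.004 in promoters (SD, n = 2 arrays).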

Results

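Histone H3 along the budding yeast genome was measured in strain MDY510, which carries H3 tagged with the Myc epitope. The cells were held in G1 with alpha factor, the mating pheromone that arrests MATa cells, and galactose was not added. Sonicated chromatin was precipitated with an anti-Myc antibody and compared on tiling microarrays with the sonicated input, called whole cell extract (WCE). The series holds 1 group of 2 arrays, replicates 1 and 2, and the labels put the IP in the Cy5 channel and WCE in the Cy3 channel of both. The question was how much H3 each part of the genome carries. Each array held 41775 probes for yeast sequence at a median spacing of 257 bp, and 40890 were kept. Median spot brightness was 34318 and 36699 in Cy5 and 36103 and 34487 in Cy3, against local backgrounds of 87.5 and 85 in Cy5 and 69 and 64 in Cy3. The number of arrays, 2, limits the precision of every value. All ratios are log2 Cy5 over Cy3, centred on each array's median, with the SD over the 2 arrays.

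Mitochondrial DNA, which is not wrapped around histones, served as the check of the channel labels, and it went against them. Its probes were brighter in the channel labelled Myc-H3 IP than in the channel labelled WCE. Their median ratio lay 4.84 ± 0.10 (SD, n = 2 arrays) above that of nuclear probes, a 28.7-fold difference over 230 mitochondrial probes. Each channel's level was taken over all 295 mitochondrial probes and all nuclear probes, with no filter. Within Cy3 the median mitochondrial signal was -5.03 ± 0.03 relative to the nuclear median, and within Cy5 it was -0.61 ± 0.01. In Cy5, 29.8% and 30.8% of these 295 mitochondrial probes were saturated on the 2 arrays, and in Cy3 0% were on either array. The size of the difference moved with the processing: it was 3.66 without saturated probes, 0.90 ± 0.19 with normexp background correction and 0.64 ± 0.58 with loess added, where the arrays gave 1.05 and 0.22. The direction was the same in each. The material is therefore named below by its label only, as the channel labelled IP and the channel labelled WCE. A positive ratio means brighter in Cy5, and every direction below is subject to this check: if the channels were exchanged, each sign would turn.

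**Figure D1:**
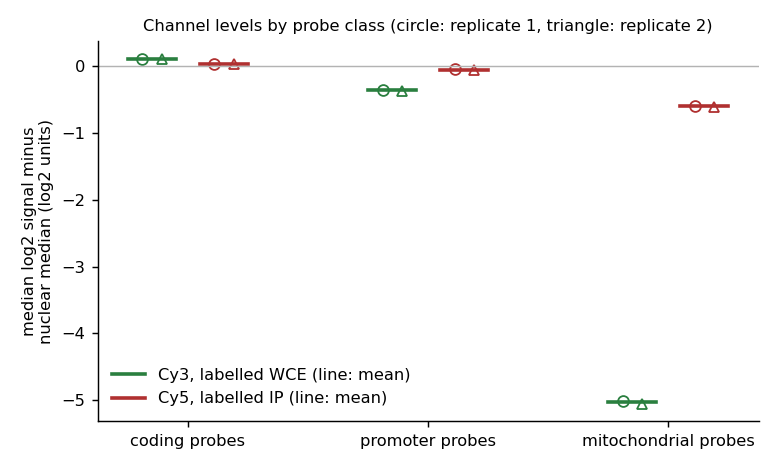
Median log2 signal of coding, promoter and mitochondrial probes minus the median of nuclear probes, in log2 units, for Cy3 (green) and Cy5 (red). All such probes on the array are included, with no filter. Circles are replicate 1, triangles replicate 2 and lines the mean of the 2 arrays; mitochondrial probes lie at -5.03 in Cy3 and at -0.61 in Cy5, and levels of different probe classes also carry the probes' own affinity.

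The 2 arrays gave nearly the same profile. Across kept probes, which are not independent replicates, Pearson's r was 0.992 and Spearman's rho 0.979, and across nuclear probes alone r was 0.988. The between-array SD of a nuclear probe was 0.05, against an SD across nuclear probes of 0.42 on each array. The between-array SD is that of the difference between the arrays divided by the square root of 2. The difference between the arrays was nearly unrelated in neighbouring probes (r = 0.03), whereas the mean ratio was related (r = 0.53). Repeated spots of 3 control probes had a larger SD within an array, 0.11 in replicate 1 and 0.09 in replicate 2. An error that both arrays share, such as that of a probe, is not part of the spread between them. The labels do not say whether the replicates came from separate cultures, so limma's p-values for probes and genes measure the spread between these 2 arrays, which may be technical. The sign-flip p-values treat chromosomes as units, and the p-values of gene lists treat genes as units. Neither kind measures the spread between cultures.

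Promoters were brighter in the channel labelled IP than coding regions were. The mean ratio was 0.31 ± 0.03 over 9074 promoter probes and -0.06 ± 0.02 over 29599 coding probes (SD, n = 2 arrays). The difference was 0.37 ± 0.01, or 1.30-fold, and was positive on 16 of 16 chromosomes, from 0.27 on chromosome 6 to 0.42 on chromosome 2. Its p in a two-sided exact sign-flip permutation test over chromosomes was 3.05e-05, the smallest that 16 chromosomes can give (7.63e-05 after Benjamini-Hochberg adjustment over 5 comparisons). The 2 arrays alone could not go below an exact p of 0.5. In 3537 of 4576 genes measured in both regions, 77.3%, the promoter ratio lay above the coding ratio. Across genes, which are not independent, the 2 regions' ratios were related with r = 0.27 and rho = 0.21. With normexp the difference was 0.24 ± 0.04, and with loess added 0.13 ± 0.12, where replicate 1 gave 0.21 and replicate 2 gave 0.04. The mean over arrays had an exact p of 3.05e-05 in both settings.

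Intergenic regions differed by the orientation of the flanking genes. Divergent promoters, which lie between the starts of a gene pair, had the highest mean ratio of these classes, 0.40 ± 0.03. Tandem promoters, upstream of a single gene, had 0.26 ± 0.03, and convergent regions, which lie between gene ends, had 0.02 ± 0.03. Divergent exceeded tandem promoters by 0.14 ± 0.001 on 15 of 16 chromosomes (exact sign-flip permutation p = 6.10e-05, adjusted 1.02e-04). Tandem promoters exceeded convergent regions by 0.24 ± 0.002 on 16 of 16 chromosomes (exact sign-flip permutation p = 3.05e-05, adjusted 7.63e-05). Both differences shrank by more than 1.5 times with normexp, to 0.06 ± 0.02 and 0.09 ± 0.05, and with loess added, to 0.05 ± 0.04 and 0.08 ± 0.07, and their means over arrays passed the same test. With loess added, replicate 1 gave 0.08 and 0.13, and replicate 2 gave 0.02 and 0.03. Intergenic regions that hold a tRNA gene, which are transcribed by RNA polymerase III, had a mean of 0.35 ± 0.03 over 1520 probes. They exceeded other intergenic regions, convergent ones included, by 0.10 ± 0.01, on 13 of 16 chromosomes (exact sign-flip permutation p = 7.32e-04, adjusted 9.16e-04). With loess after normexp this difference was 0.02 ± 0.02 (exact p = 0.00397), with 0.0373 in replicate 1 and 0.0070 in replicate 2.

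Coding probes within 20 kb of a chromosome end had a mean of -0.08 ± 0.02 and internal coding probes one of -0.06 ± 0.02. The difference of -0.02 ± 0.003 did not pass the test (exact sign-flip permutation p = 0.395), and 9 of 16 chromosomes had the higher value near their ends. With a window of 10 kb the difference was -0.07 ± 0.002 and with 30 kb -0.000073 ± 0.0019 (exact permutation p = 0.992 and 0.895). The test weighs chromosomes equally, so the p of 0.992 does not test the pooled value of -0.07. With 60-nt probes only, a setting chosen after seeing the data, it was -0.04 with an exact permutation p of 0.0314.

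**Figure D2:**
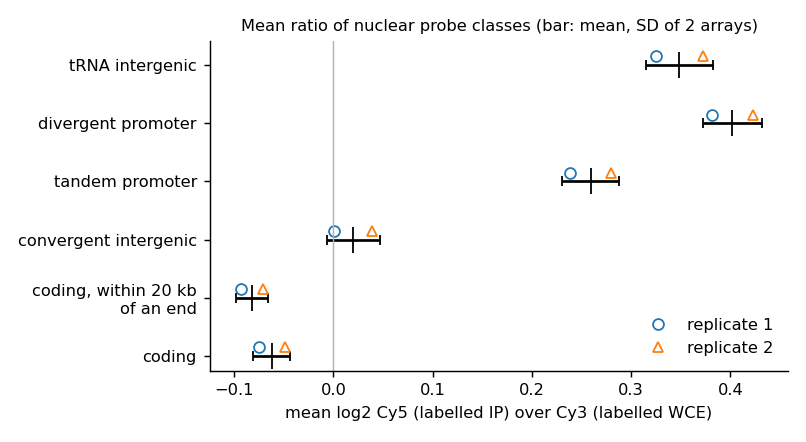
Mean log2 ratio of Cy5 (labelled IP) over Cy3 (labelled WCE) for 6 classes of nuclear probes. Black bars are the mean and SD of 2 arrays, circles replicate 1 and triangles replicate 2; divergent promoters lie at 0.40, tandem promoters at 0.26, convergent regions at 0.02 and coding regions at -0.06.

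Within genes the ratio was lower at inner than at outer probes, among the positions measured. In 1160 genes with at least 8 coding probes, the mean was 0.39 ± 0.03 at the third probe upstream of the coding region, 0.28 ± 0.03 at the second and 0.18 ± 0.03 at the first. The first coding probe had 0.03 ± 0.02 and the fourth -0.18 ± 0.02. Counted from the end of the gene, the fourth probe had -0.21 ± 0.02 and the last one -0.07 ± 0.02. The upstream means rest on 366, 704 and 1087 genes, since short upstream regions hold fewer probes.

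**Figure D3:**
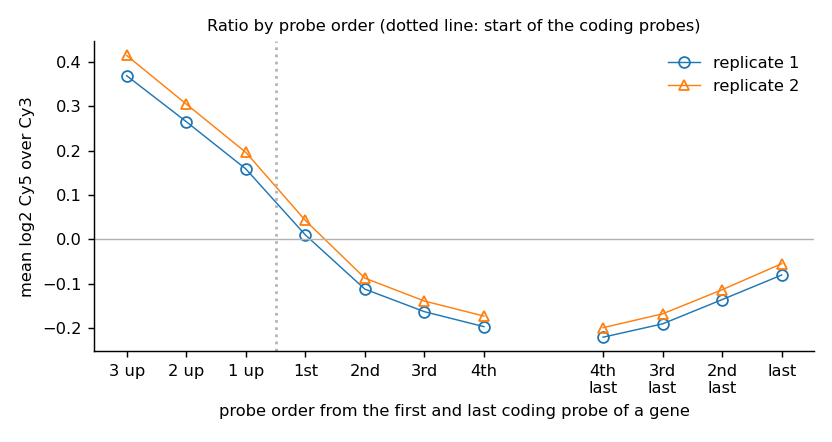
Mean log2 ratio of Cy5 over Cy3 by probe order, from 3 probes upstream of the first coding probe to the fourth coding probe, and from the fourth last to the last, in 1160 genes with at least 8 coding probes. Circles are replicate 1 and triangles replicate 2; on both arrays the values fall from upstream into the gene and are higher again at its last probe.

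Coding regions of 4996 genes were tested against the array median. Of these, 1744 were higher in the channel labelled IP, 2451 were lower and 801 did not pass (limma, adjusted p under 0.05). The largest positive ratio in the main setting was that of SHR5, 2.77 ± 0.08, which encodes a subunit of the palmitoyltransferase for Ras proteins (chromosome 15, probes from 109305 to 109775). Next came YKR041W with 2.26 ± 0.04, and HSP150, a secreted cell wall protein, with 1.89 ± 0.02. PHO4, the transcription factor of the phosphate response, had 1.67 ± 0.04 on chromosome 6, and RRN5, a subunit of the upstream activation factor of RNA polymerase I, had 1.61 ± 0.05. The lowest ratios were smaller in size. VPS28, of the ESCRT-I sorting complex, had -0.72 ± 0.07 (chromosome 16, probes from 428084 to 428469), VPS38 -0.67 ± 0.02 and the RNA polymerase III subunit RPC11 -0.64 ± 0.02. They were followed by the ribosomal protein gene RPS22B with -0.64 ± 0.09, the transcription factor AZF1 with -0.63 ± 0.03, LSM4 with -0.61 ± 0.02 and COS12 with -0.61 ± 0.04. RAD61 had -0.59 ± 0.04, YCR102C -0.59 ± 0.03 and SNC1 -0.59 ± 0.02. Many of these values rest on few probes: 2 each for SHR5, HSP150, VPS28, RPC11, RPS22B, YCR102C and SNC1, and 3 each for YKR041W, PHO4 and LSM4. RRN5, VPS38 and COS12 have 5, RAD61 6 and AZF1 9. The SD over arrays does not measure the spread among a gene's probes. Coordinates are those of the array, whose genome build is not given in the sources used here.

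Promoters of 5171 genes gave 3663 higher, 837 lower and 671 that did not pass (limma, adjusted p under 0.05). The highest in the main setting was that of SED1, a major cell wall glycoprotein, with 2.35 ± 0.07 over 3 probes on chromosome 4 from 599717 to 600568. The divergent promoter of HOG1, the osmotic stress kinase, and CCW12, another cell wall glycoprotein, had 2.24 ± 0.06 over 5 probes, which cannot be assigned to either gene. KTI12 had 2.22 ± 0.06 and VHR2 2.09 ± 0.03. The lowest were YOR097C with -1.05 ± 0.01, the splicing factor gene CDC40 with -0.99 ± 0.01, ACM1 with -0.87 ± 0.01 and the promoter shared by EST2 and TAD3 with -0.82 ± 0.05. Each of these lowest promoters rests on 1 probe.

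These gene counts depended on the processing. With normexp, which starts from the signals before detrending and dye normalisation, 8 coding regions were higher and 2 lower, and no promoter passed (limma, 0 of 5171; at an unadjusted p under 0.05, 704 higher and 31 lower). With loess added, 0 coding regions and 0 promoters passed (limma; unadjusted, 432 and 155 coding regions and 81 and 0 promoters). Agreement between the arrays was r = 0.29 with normexp and 0.97 with loess added, against 0.992 in the main setting. With loess added, every class difference was smaller in size in replicate 2, as for mitochondrial DNA (0.22 against 1.05). The arrays thus agreed in profile and differed in scale, so values far from 0 also differed more between them. The counts of 0 with loess therefore do not show a lack of agreement in profile. Whether the normexp fit suits arrays this bright was not checked. The lost calls and turned signs therefore cannot be told apart from a poor fit. Under normexp the mean of VPS28, RPS22B, LSM4, SNC1 and of each of the 5 lowest promoters was positive. At the level of probes, 15888 nuclear probes were higher and 16109 lower, and 3895 and 3094 of them by at least 0.5. With normexp, 260 of all 40890 kept probes were higher and 115 lower, against 16115 and 16110 in the main setting.

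Ribosomal protein genes and genes of glycolysis and respiration had high ratios. Camera called these lists with its preset correlation, and with an estimated one each list had an adjusted p of 0.978 in coding regions and 0.970 in promoters. The estimated correlation could not tell lists apart, as given below. List differences here and below are those of the main setting unless another is named. Ribosomal protein genes exceeded other genes by 0.31 ± 0.01 in coding regions, where 92 of 101 were higher and 5 lower, and by 0.42 ± 0.01 in promoters, where 127 of 136 were higher and 1 lower. RPL15A had 0.95 ± 0.04 and RPS4A 0.89 ± 0.02 in their coding regions, and the promoters of RPL6B and RPS16B had 1.68 ± 0.04 and 1.41 ± 0.07. RPS22B lay far below, as given above, and the RPL22A promoter had -0.12 ± 0.04, which was 0.19 with normexp. Centred on the mode, the RPL22A promoter kept -0.12 and did not pass (limma adjusted p = 0.0727). Genes of glycolysis and fermentation exceeded other genes by 0.41 ± 0.003 in coding regions, where 14 of 18 were higher and 1 lower, and by 0.54 ± 0.004 in promoters, where 19 of 19 were higher. TDH3, a glyceraldehyde-3-phosphate dehydrogenase, had 1.28 ± 0.04 in its coding region and 1.46 ± 0.02 in its promoter, and the coding region of the pyruvate decarboxylase gene PDC1 had 1.01 ± 0.01. PFK2 was lower with -0.10 ± 0.02, a call lost when centred on the mode, where it kept -0.10 (limma adjusted p = 0.0999). The PFK1 coding region, at -0.01 ± 0.01, did not pass, but with 60-nt probes only it was lower at -0.14 (limma adjusted p = 2.37e-13). Genes of respiration exceeded other genes by 0.17 ± 0.002 in coding regions, with 20 of 30 higher and 4 lower, and by 0.21 ± 0.01 in promoters, with 37 of 39 higher and 2 lower. ATP17 had 0.81 ± 0.05 in its coding region and the citrate synthase gene CIT1 had 1.07 ± 0.03 in its promoter, while the coding regions of IDH2 and KGD1 had -0.29 ± 0.001 and -0.23 ± 0.01.

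In limma's camera test with a preset correlation of 0.01, adjusted over the 16 lists tested in coding regions, the adjusted p was 5.34e-20 for ribosomal protein genes, 3.29e-10 for glycolysis and 0.00218 for respiration. Over the 18 lists tested in promoters it was 3.39e-15, 3.66e-07 and 0.0130. Genes that share a divergent promoter entered these promoter tests and counts as separate members, although they rest on the same probes. With an estimated correlation no list was called: the adjusted p was 0.978 for every list in coding regions and 0.970 for every list in promoters. That fit had 1 residual degree of freedom, too few to estimate a correlation between genes. It gave 0.970 alike to promoter lists that differed by 0.54 and by -0.29, so it bears neither for nor against a call. Adjusted over the list alone, the counts were the same except for respiration in coding regions, with 19 higher, and for G2/M and M/G1 genes in promoters, with 2 lower in place of 3. Counts of list members are to be read against all genes, of which 1744 of 4996 coding regions and 3663 of 5171 promoters were higher. Within genes the coding ratio was lower at inner than at outer probes, as given above. Neither camera nor the random lists matched genes on length or number of probes. A difference of a coding list, here and below, therefore cannot be told apart from an effect of gene length. Among 60-nt probes only, the glycolysis difference in coding regions was 0.11 with an adjusted p of 0.330 and the respiration difference in promoters 0.16 with 0.0724, while with normexp the respiration difference in coding regions was 0.07 with 0.0566 (camera, preset correlation).

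Promoters of pheromone response genes, many of which are induced by alpha factor, also had high ratios. They exceeded other promoters by 0.50 ± 0.003, and 30 of 31 were higher and 0 lower (camera adjusted p = 1.20e-08, and adjusted p = 0.970 with an estimated correlation). MFA1, which encodes the a-factor pheromone, had 1.67 ± 0.03 and GPA1, the alpha subunit of the pheromone receptor's G protein, 1.65 ± 0.03. The promoter of the cell fusion gene FUS1 had 0.27 ± 0.04, and that of CHS1 did not pass, at 0.00 ± 0.02. The coding regions of the same list showed no common shift, at 0.04 ± 0.01 from other genes with 12 of 28 higher and 14 lower (camera adjusted p = 0.736, and adjusted p = 0.978 with an estimated correlation). ASG7 and AGA1 were its highest members, at 0.77 ± 0.06 and 0.62 ± 0.01, and PRM10 and STE12 its lowest, at -0.45 ± 0.02 and -0.40 ± 0.02, with FUS1 at -0.18 ± 0.003. BAR1, whose coding ratio is not read as described below, is a member of the list in both regions. Among the 4 promoters of alpha-cell-specific genes, MF(ALPHA)1 was lower at -0.29 ± 0.004, SAG1 was higher at 0.20 ± 0.01, and the list did not pass (difference -0.27, camera adjusted p = 0.365).

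Promoters of seripauperin and related cell wall genes, a family repressed in air, lay below other promoters by -0.29 ± 0.01, with 9 of 25 higher and 11 lower than the array median (camera adjusted p = 0.00291, and adjusted p = 0.970 with an estimated correlation). PAU3 was lowest with -0.50 ± 0.01, and TIR3 had 0.50 ± 0.05. Their 6 measured coding regions differed by 0.02 ± 0.02 (camera adjusted p = 0.900). Members of this family are close in sequence, so their signals are uncertain. Promoters of meiosis and sporulation genes lay -0.17 ± 0.01 from other promoters, with 25 of 44 higher and 13 lower than the array median (camera adjusted p = 0.0438, and adjusted p = 0.970 with an estimated correlation). This call was not made against random lists matched on Cy3 signal (adjusted p = 0.378) nor with 60-nt probes only, where the difference was as large (-0.18, camera adjusted p = 0.0510). The random lists compare medians and are matched on the denominator of the ratio, so they do not repeat the camera test. SPO19 had -0.43 ± 0.02 and SGA1 0.88 ± 0.06. In coding regions the list differed by -0.02 ± 0.002 (camera adjusted p = 0.852).

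Galactose genes, which were not induced here, did not stand apart as a list. Their difference was -0.01 ± 0.01 in coding regions, with 4 of 12 higher and 4 lower, and -0.10 ± 0.01 in promoters, with 7 of 12 higher and 2 lower (camera adjusted p = 0.939 and 0.623). Of all 5171 promoters, 3663 were higher than the array median. In coding regions GAL1 had 0.14 ± 0.04, GAL10 -0.12 ± 0.03 and GAL7 -0.20 ± 0.02. The promoter that GAL1 and GAL10 share had 0.37 ± 0.01, over 2 probes on chromosome 2 from 278441 to 278711, and the GAL2 promoter had -0.43 ± 0.04. With 60-nt probes only, GAL1 had 0.03 in its coding region and did not pass (limma adjusted p = 0.156). With centring on the mode in place of the median, GAL10 in its coding region kept -0.12 and did not pass (limma adjusted p = 0.0551). Phosphate genes did not pass as a list in either region (differences 0.03 ± 0.02 and 0.04 ± 0.02, camera adjusted p = 0.852 and 0.832). The PHO5 promoter, a much studied site of nucleosome loss on phosphate starvation, had 0.42 ± 0.02, and its coding region, at 0.02 ± 0.01, did not pass. That coding region passed as higher with 60-nt probes only (0.07) and without saturated probes (0.04), and its sign turned with normexp (-0.06; limma adjusted p = 2.14e-04, 0.00477 and 0.820). The PHO84 promoter had 1.06 ± 0.04.

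**Figure D4:**
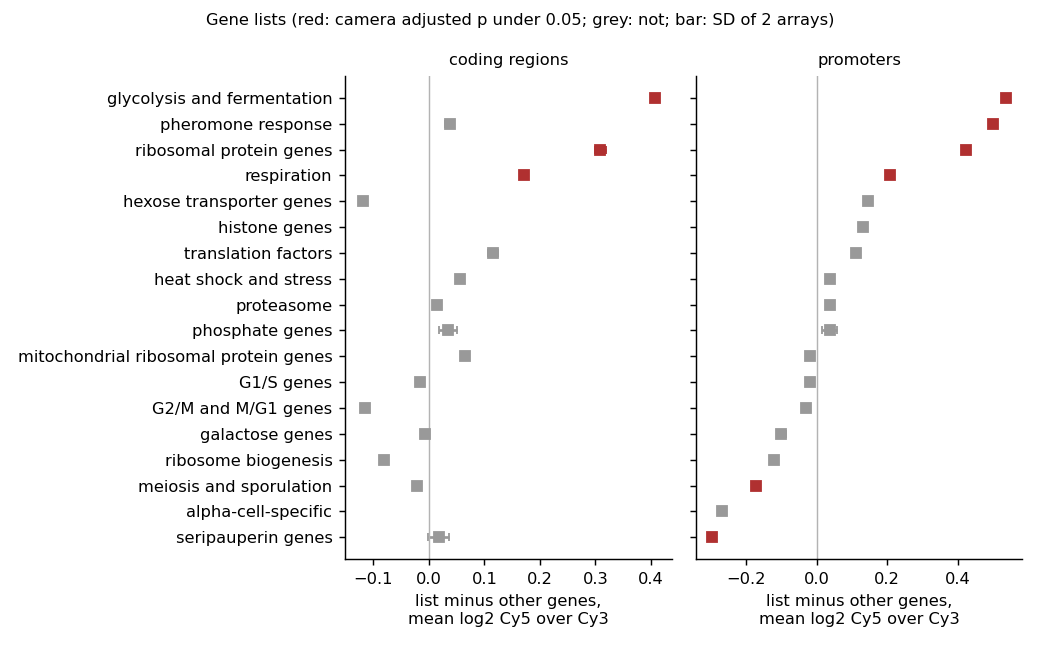
Mean log2 ratio of Cy5 over Cy3 of each gene list minus that of all other genes measured, in coding regions (left) and promoters (right). Squares are the mean and bars the SD of 2 arrays, and red marks an adjusted p under 0.05 in camera with the preset correlation. No list was called with an estimated correlation, a setting that could not tell lists apart.

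The loci at which the strain may differ from the reference were read from their signal in both channels. BAR1, which encodes the protease that degrades alpha factor, lay far below the nuclear median, at a mean log2 level of -5.37 ± 0.02 in Cy3 and -4.99 ± 0.04 in Cy5, over 7 probes on chromosome 9 from 322565 to 324053. Of these, 2 were not well above background in Cy3 on both arrays, so the Cy3 level is an upper bound. Its coding ratio, 0.43 ± 0.14 over the 5 probes kept, comes from such low signals and is not read as a measure of H3. The single coding probe of HHT1, 1 of the 2 genes for histone H3, lay at -3.21 ± 0.10 in Cy3 and -2.71 ± 0.13 in Cy5, whereas that of HHT2 did not lie below (log2 level 0.78 ± 0.05 in Cy3). The coding probes of URA3, LEU2, HIS3, TRP1, LYS2, ADE2, CAN1 and HO were well above background. Levels of different probes also depend on the probe, so these levels are not read as amounts of DNA. COS7, a subtelomeric gene of a family with close copies, was the only gene with all its coding probes not well above background in Cy3 on both arrays.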

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

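The settings without saturated probes, with 60-nt probes only, with dimness in both channels and with the turned sign were chosen after seeing the data, and the others were planned. No paired analysis was possible because the series holds a single group. The promoter minus coding, divergent minus tandem, tandem minus convergent and tRNA differences kept their sign and passed the exact sign-flip test in every setting run except the turned sign, which makes the first -0.37 by construction. Each array alone gave 0.366 to 0.381, 0.142 to 0.144, 0.238 to 0.241 and 0.0967 to 0.105 for these, -0.0224 to -0.0185 near chromosome ends and 4.77 to 4.91 for mitochondrial DNA. A count of calls was not possible with 1 array. With normexp, the agreement between arrays fell to r = 0.29, 260 probes were above and 115 below the median, 8 coding regions above and 2 below, and 0 promoters above and 0 below (limma). The mitochondrial difference was 0.90, and 2 lists were lower in coding regions. Signs turned for VPS28 (0.0925), RPS22B (0.29), LSM4 (0.0634) and SNC1 (0.0656) in coding regions, and for the promoters of YOR097C (0.0764), CDC40 (0.17), ACM1 (0.11), EST2 and TAD3 (both 0.20) and RPL22A (0.19). The PHO5 coding region, which passed in neither setting, turned to -0.0580. Of 82 named gene values, 63 kept their sign and no longer passed, 8 kept sign and side and 11 changed sign. With loess added, r was 0.97, the mitochondrial difference 0.64, and 0 probes, 0 coding regions and 0 promoters were above and 0 below (limma; 0 probes also at an unadjusted p under 0.05), with 2 lists lower in coding regions, and 79 of the named gene values no longer passed. Centring on the mode gave 1155 coding regions above the median, against 1744. With no background filter the mitochondrial difference was 4.43, and without saturated probes 3.66, with 1 list lower in coding regions. With 60-nt probes only, the difference near chromosome ends passed the test at -0.0399 (exact p = 0.0314, range over its alternatives 0.0314 to 0.992), and 1 list was lower in promoters. With at least 1 coding probe per gene, 5 lists were higher and 2 lower in coding regions. Camera with an estimated correlation called 0 lists higher in coding regions, 0 higher in promoters and 0 lower in promoters (0 at an unadjusted p under 0.05 too). As given above, that setting could not tell lists apart. Random matched lists gave 1 lower in coding regions and 1 lower in promoters. With a limit of 2 background SDs, 0 genes were dim in the channel labelled WCE, against 1. Other signs turned only where neither setting passed. With normexp these were the coding lists of meiosis and sporulation (0.0205), phosphate (-0.0139) and seripauperin genes (-0.0472), and the promoter lists of mitochondrial ribosomal proteins (0.0052), G2/M and M/G1 genes (0.0107) and heat shock (-0.0032). With loess added, they were the promoter lists of mitochondrial ribosomal proteins (0.0065), histones (-0.0260) and phosphate genes (-0.0094), the PHO5 coding region (-0.0091) and the CHS1 promoter (-0.00085). Without replicate 1, they were the PFK1 coding region (0.00042) and the CHS1 promoter (-0.0105), values with no test, with -0.0121 and 0.0133 without replicate 2. With at least 1 coding probe, the coding lists of proteasome (-0.0111) and seripauperin genes (-0.0077) turned. Without saturated probes, the coding lists of galactose (0.0162) and seripauperin genes (-0.0050) and PFK1 (0.0061) turned. With 60-nt probes only, the coding lists of galactose (0.0576), G1/S (0.0040) and meiosis and sporulation genes (0.0410) and the promoter list of heat shock genes (-0.0163) turned. Against random lists, medians turned against the means for the coding lists of pheromone response (-0.0055), galactose (0.0513), G1/S (0.0190) and phosphate genes (-0.0031), and for the promoter lists of mitochondrial ribosomal proteins (0.0163) and G1/S genes (0.0186). Except where the setting's construction shows it, the cause was not tested. The authors' value table and the filter on both channels moved no result. A correction for base composition, other promoter windows and probes with several matches were not run, since they need probe sequences or gene positions on the array's coordinates.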

Other observations

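The tests of the mitochondrial ratio, of base composition and of dim neighbours were chosen after the values were seen, whereas the tRNA test and the test without saturated probes were written before their results. The classes by gene order that the tRNA test used were themselves chosen after seeing the data. Several groups of genes not described above held members far from the array median. Among heat shock and stress genes, the promoters of MSN4, a stress transcription factor, and HOR7 had 1.36 ± 0.06 and 1.06 ± 0.04, and the coding region of the small chaperone gene HSP42 had -0.53 ± 0.02. The list itself did not pass (differences 0.06 in coding regions and 0.04 in promoters, camera adjusted p = 0.383 and 0.793). Translation factor genes differed by 0.12 in coding regions and 0.11 in promoters (camera adjusted p = 0.148 and 0.365), and the coding list passed as higher with normexp, with loess added, with at least 1 coding probe per gene, without saturated probes and with 60-nt probes only (0.0360, 0.0283, 0.0432, 0.0374 and 0.0466; differences 0.10, 0.06, 0.16, 0.13 and 0.15). It did not pass against random matched lists (adjusted p = 0.0512) nor with an estimated correlation (0.978). Its members include SSB1 at 0.55 ± 0.04 in its coding region and, among promoters, EFT2 at 1.04 ± 0.05. Proteasome genes differed by 0.01 and 0.04 (camera adjusted p = 0.891 and 0.793), with the PRE7 promoter at 1.28 ± 0.01. Mitochondrial ribosomal protein genes differed by 0.07 and -0.02 (camera adjusted p = 0.230 and 0.856). Ribosome biogenesis genes differed by -0.08 in coding regions, with 40 of 61 lower and 11 higher, and by -0.12 in promoters (camera adjusted p = 0.115 and 0.180). The coding list passed as lower against random matched lists (adjusted p = 0.0120), with normexp (camera adjusted p = 0.0265), with loess added (0.0239) and with at least 1 coding probe per gene (0.0446), where the last 3 gave differences of -0.07, -0.04 and -0.11. It did not pass with an estimated correlation (0.978), without saturated probes (0.0859) nor with 60-nt probes only (0.102), and UTP22 and YTM1 had -0.42 ± 0.02 and -0.43 ± 0.06.

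The 2 lists of cell cycle genes did not pass in the main setting. G1/S genes differed by -0.02 in both regions (camera adjusted p = 0.891 and 0.856). G2/M and M/G1 genes differed by -0.12 in coding regions, with 19 of 26 lower and 2 higher, and by -0.03 in promoters (camera adjusted p = 0.0982 and 0.832). Their coding list passed as lower with normexp (0.0265), with loess added (0.0239), with at least 1 coding probe per gene (0.0446) and without saturated probes (0.0374), at differences of -0.09, -0.05, -0.14 and -0.12. It did not pass against random matched lists (adjusted p = 0.388), with 60-nt probes only (0.208) nor with an estimated correlation (0.978). The coding regions of EGT2 and BUD4 had -0.35 ± 0.02 and -0.29 ± 0.01, and the MCM3 promoter had 1.34 ± 0.01. Histone gene promoters differed by 0.13 (camera adjusted p = 0.447). The shared promoter of HTA1 and HTB1 had 0.74 ± 0.03 and that of HHT2 and HHF2 0.70 ± 0.01, while the promoter of CSE4, the centromeric H3 variant, had -0.63 ± 0.05. Hexose transporter genes differed by -0.12 in coding regions and 0.14 in promoters (camera adjusted p = 0.230 and 0.372), with HXT1 at -0.48 ± 0.04 in its coding region and the promoters of HXT6 and HXT7, which are near-identical copies, at 1.39 ± 0.04 and 1.38 ± 0.04. With an estimated correlation the adjusted p was 0.978 in coding regions and 0.970 in promoters for each of these lists. Coding lists were not matched on gene length, as given above.

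Mitochondrial DNA and promoters were brighter in the channel labelled IP, although mitochondrial DNA carries no histones, and without saturated probes promoters still exceeded coding regions by 0.38 (exact sign-flip permutation p = 3.05e-05). Carry-over of DNA into an IP in proportion to the input would leave the mitochondrial ratio at or below the nuclear one, and is argued against by the difference of 4.84 ± 0.10, which was above 0 on each array and in every setting. Carry-over that favours mitochondrial DNA was not tested and stays open. It could raise the Cy5 level but would leave the low Cy3 level, -5.03 ± 0.03 relative to the nuclear median, unexplained. A hypothesis is that the channels hold the opposite material to the labels: it predicted that intergenic regions with a tRNA gene, known to be poor in nucleosomes, would be higher in Cy5, and the difference was 0.10 (exact sign-flip permutation p = 7.32e-04). The regions compared include convergent ones, at a mean of 0.02, and the tRNA mean, 0.35, lay near that of all promoters, 0.31. Orientation and length of the regions were not matched, so this result cannot decide whether the channels were exchanged. A bias by base composition stays open for promoters and mitochondrial DNA, which are AT-rich, since no probe sequences were used: among 60-nt probes tandem promoters exceeded convergent regions by 0.22, which composition alone could give only if the classes differ in it. The design holds a single group and no dye swap, so no biological explanation was tested.

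Nuclear probes that were dim in both channels had a dim neighbour more often than by chance, although most had none. Of 36 probes not well above background in either channel on both arrays, 27.8% had a dim neighbour, against a median of 0% and a highest value of 11.1% in 10000 random placements. This argues against scattered poor probes as the only cause. For the 72.2% without a dim neighbour scattered poor probes stay open. Sequence missing from this strain, which would give runs of dim probes, stays open for all 36. At a looser limit, 272 nuclear probes lay at least 8-fold below the nuclear median in both channels, and 41 of them lay in 9 runs of 3 or more. These runs include BAR1, a stretch between SRD1 and MAK32 on chromosome 3 from 149974 to 151480 and a stretch between HXT7 and HXT6 on chromosome 4 from 1157748 to 1158970. Probes of poor design for repeated sequence would also lie together and were not tested.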
